A study of Homo sapiens with 12 samples.

How the data were processed

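The data were 12 polyadenylated RNA libraries of LX2 cells, an established human hepatic stellate cell line, in 3 groups of 4 as the labels give them: untreated cells (control), cells given TGFb, and cells given the compound STINGX before TGFb. Per the labels' protocols, the libraries were made with a strand-specific TruSeq mRNA kit and sequenced as read pairs on a NovaSeq instrument. The submitters' processing notes name cutadapt (an adapter trimmer), HISAT2 (a spliced aligner), StringTie (a transcript assembler and quantifier) and edgeR, without versions, and the genome build GRCh38. The role and order of each tool, their parameters, the annotation release and whether strand was used in counting are not given in the sources used here.

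The authors deposited estimated counts per gene for 60612 genes, estimated counts per transcript for 229420 transcripts, and a table of FPKM values beside the same gene counts. The deposited estimated counts were whole numbers, and the sum over the transcripts of a gene equalled its gene count in every library. In the deposited FPKM table a gene with a count of 0 is listed at 0.0001. A count of 1 stood beside FPKM values as low as 1e-06, so the counts were derived from coverage and are not direct tallies of fragments. No value column was left without a sample. The estimated counts were the basis of every main result, and the FPKM values were used only as an alternative. Reads that could belong to overlapping genes, or to a gene and a near-identical copy, were divided by the authors' software before deposit, so among the largest changes genes that overlap another on the same strand are named as uncertain. Since use of strand in counting is not stated, those that overlap another on the opposite strand are treated likewise. Other genes that overlap another carry the same uncertainty, and their overlaps are not listed.

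Library totals ran from 54035320 to 70787741 counts. At that depth 1 count equals between 0.0141 and 0.0185 CPM, the unit of counts scaled to a common library total. Where a group had a count of 0 in all 4 libraries, the fold was computed against a floor of 3 counts over the group and is written as "at least". Such bounds cover counting error only, because the fragments carried no molecular identifiers. Replicates of a group were compared pair by pair before averaging, and every pair differed by far more than counting noise (chi-square per degree of freedom from 42.1 to 89.3). The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

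Genes were tested with edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 21328, libraries were scaled by TMM (trimmed mean of M-values), dispersions were estimated robustly, and the quasi-likelihood F test of glmQLFit and glmQLFTest was applied to all 12 libraries together (9 residual degrees of freedom), with an adjusted p under 0.05 as the threshold. The fixed plan named the older form of the quasi-likelihood fit as an alternative, so the newer form was used for the main results (legacy = FALSE). The common dispersion was 0.0782, a biological coefficient of variation of 28.0%. CPM values are scaled by the TMM library sizes and are given as mean ± SD of 4 libraries. Log2 fold changes carry a standard error (SE) derived from the test, the size of the change over the square root of its F statistic.

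The comparisons, the tests, 25 gene lists, the alternatives and the rule for naming genes were set before the data were examined. The lists covered fibrillar collagens and matrix glycoproteins, matrix crosslinking and turnover, the contractile cytoskeleton, direct TGF-beta and SMAD targets, YAP and TEAD targets, integrins and focal adhesion, interferon-stimulated genes, cGAS-STING pathway components, NF-kappaB and inflammatory cytokines, mitochondrially encoded messenger RNAs, mitochondrial DNA upkeep, nuclear-encoded oxidative phosphorylation, glycolysis, serine, proline and glutamine metabolism, the unfolded protein and integrated stress response, NRF2 and oxidative stress, the aryl hydrocarbon receptor, cholesterol biosynthesis and uptake, the cell cycle, p53 targets, quiescent stellate cell markers, and markers of hepatocytes, endothelium, macrophages and leukocytes, and cholangiocytes and epithelium. Of the 748 distinct genes of the lists and of a panel of single genes, 745 were matched by symbol and 3 by identifier. Each list was tested against all other genes with camera at its preset inter-gene correlation of 0.01, adjusted over the 25 lists, and again with an estimated correlation. The rotation test fry was computed beside it.

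For each comparison the rule named the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 2 CPM, a symbol, and all 4 libraries of one group beyond all 4 of the other, up to 4 changed members of each list by size of change, and a panel of 26 genes whatever their result. From these the text gives the most informative. Some genes that the rule names are not reported here. Coordinates are those of the deposited tables (GRCh38, counted from 1).

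To ask whether genes changed by TGFb moved back with STINGX, genes were chosen on 2 of the 4 TGFb libraries and the shift was measured with the other 2, over all 6 ways of halving the group, because both comparisons otherwise share the TGFb libraries with opposite sign. The same quantities were computed on simulated counts without a STINGX effect. The overlap of comparisons that share libraries was set beside the product expected of independent lists and the value with the shared libraries split, and the covariance of their fold changes beside simulated groups without effects.

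The test was checked on simulated counts for 20311 genes with known changes. For TGFb against control it recovered 46.0% of genes changed 1.5-fold, 72.0% at 2-fold and 88.0% at 4-fold, with 9 of 20111 unchanged genes called. For STINGX with TGFb against TGFb the shares were 38.5%, 70.8% and 80.8%, with 7 of 20211 called, and for STINGX with TGFb against control 54.2%, 73.1% and 95.8%, with 3 of 20211 called. Each level held 50 changed genes in the first comparison and 24 to 26 in the others. Far fewer genes were changed than passed in the real data. The adjusted threshold was therefore stricter in the simulation, and these shares may be too low.

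Alternatives were DESeq2 size factors, upper quartile or library size alone in place of TMM, no filter on low counts or at least 1 CPM in 4 libraries, the DESeq2 1.42.0 Wald test, limma 3.58.1 with voom, the older quasi-likelihood fit, only the 8 libraries compared, the replicate number as a block, limma on log2(FPKM + 1) with and without a filter or on log2(FPKM + 0.1) with one, gene counts summed from transcripts, and each of the 12 libraries left out in turn. The sums over transcripts equal the gene counts and could not change a result, so they are left out where settings are counted. The transcript counts were otherwise used only for the 2 forms of XBP1, which were told apart by the transcript sequences of GENCODE release 29, a different release from the deposited annotation. After the main results were seen, 2462 Gene Ontology terms of 15 to 300 tested genes, as the deposited table assigns them to genes, were tested with camera as an exploration. Tables were handled in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.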

Results

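Polyadenylated RNA of LX2 cells, an immortalised line of human hepatic stellate cells that lays down matrix when stimulated, was measured in 12 libraries. The series is concerned with mitochondrial DNA and the STING pathway, an innate sensor of cytosolic DNA, in stellate cell activation. Per the labels, cells were seeded, starved of serum for 16 h from 24 h onward, and then left untreated (control, 4 libraries), given TGFb at 5 ng/ml for 16 h (TGFb, 4 libraries), or given the code-named compound STINGX at 10 µM for 3 h before the same TGFb treatment (STINGX with TGFb, 4 libraries). There was no group given STINGX alone, so its effect was measured only in the presence of TGFb. Library totals ran from 64151449 to 66738764 counts in control, from 54035320 to 63193549 with TGFb and from 58174812 to 70787741 with STINGX and TGFb. Means are given ± SD with n = 4 in each group. Mitochondrially encoded genes took 10.7 ± 0.514%, 9.05 ± 0.292% and 8.26 ± 0.138% of the counts, and the 10 most abundant genes 10.1 ± 0.300%, 10.2 ± 0.0620% and 8.42 ± 0.0900%. The first principal component (27.7% of the variance) and the next (23.4%) placed the 3 groups apart.

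The comparison of TGFb with control asked what the cytokine changed in these cells. TGFb raised matrix, contractile and SMAD target genes. FN1, which encodes fibronectin, rose from 2102 ± 36.4 to 15010 ± 74.3 CPM, and COL1A1, a chain of type I collagen, from 2307 ± 16.4 to 6367 ± 121 CPM. Interferon-stimulated genes rose as a group, and inflammatory genes such as CXCL8 fell. Of 21328 genes tested, 5543 passed an adjusted p under 0.05 (2813 higher, 2730 lower), of which 728 were at least 2-fold higher and 759 at least 2-fold lower. The 4 libraries of each group did not overlap for 27.1% of genes, where chance gives 2.86%.

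The largest rises were those of FOXS1, a forkhead transcription factor (ENSG00000179772, chromosome 20, 31844303 to 31845604, log2 fold change 7.51 ± 0.31 SE, adjusted p = 1.68e-12), ISLR2 (5.77), EGR2 (5.09), SH2D2A (4.90), PMEPA1, a feedback inhibitor of TGF-beta signalling (4.83), and UNC5B (4.09). The largest falls were those of the cytokine IL24 (ENSG00000162892, chromosome 1, 206897443 to 206904139, -5.01 ± 0.58, adjusted p = 2.15e-05), EVI2B (-3.96), DTNA (-3.82), SERPINB2 (-3.44), PCDHGA8 (-3.38) and EVI2A (-3.29). Several of these are uncertain because their reads could belong to a neighbour. PCDHGA8 overlaps 23 tested protocadherin genes on its own strand, EVI2A and EVI2B overlap AC134669 on the same strand and NF1 on the other, and SERPINB2 overlaps SERPINB10. ISLR2, SH2D2A, PMEPA1 and IL24 overlap a tested gene on the opposite strand, and UNC5B and DTNA only genes that were not tested. The fall of PCDHGA8 (adjusted p = 0.0111) did not pass with limma-voom (adjusted p = 0.107) or on unfiltered FPKM (0.0695), in a range of 1.41e-05 to 0.107 over the 11 other settings that could test it. Its log2 change ran from -4.85, without TGFb replicate 2, to -2.92 with 1 library left out. That of FOXS1 became 8.29 without control replicate 2 and that of IL24 -6.72 without TGFb replicate 4.

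Of 39 direct TGF-beta and SMAD targets, 32 rose and 1 fell (35 and 1 adjusted over the list alone), with a median log2 change of 1.25 (camera adjusted p = 1.06e-46). NOX4, an NADPH oxidase, rose from 0.0475 ± 0.0611 to 2.83 ± 0.416 CPM, LTBP2 from 18.2 ± 1.01 to 154.5 ± 5.31 CPM, and the inhibitory SMAD7 from 17.3 ± 3.00 to 108.1 ± 3.63 CPM. The log2 change of NOX4 was 5.89, and 7.00 without control replicate 1. Of 30 fibrillar collagens and matrix glycoproteins, 19 rose and 7 fell (20 and 7 adjusted over the list alone; median 0.90, adjusted p = 5.7e-14). BGN, which encodes biglycan, rose from 3.31 ± 0.554 to 34.1 ± 1.97 CPM and VCAN, which encodes versican, from 16.9 ± 1.14 to 135.0 ± 10.2 CPM. COL3A1, a chain of type III collagen, went against the list and fell from 584.4 ± 15.2 to 350.8 ± 5.37 CPM. Of 27 contractile and myofibroblast genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.43, adjusted p = 1.78e-12). TAGLN rose from 98.3 ± 9.71 to 524.1 ± 41.7 CPM and ACTA2, smooth muscle actin, from 31.3 ± 2.5 to 45.0 ± 2.27 CPM, while SYNPO2 fell from 5.98 ± 1.32 to 1.54 ± 0.821 CPM. Integrins and focal adhesion genes rose in 16 and fell in 2 of 23 cases, the same counts adjusted over the list alone (median 0.32, adjusted p = 2.11e-06). ITGA11 went from 16.3 ± 2.26 to 59.9 ± 3.37 CPM and ITGB8 from 7.05 ± 0.792 to 1.31 ± 0.215 CPM. Of 25 serine, proline and glutamine genes, 10 rose and 3 fell, also adjusted over the list alone (median 0.10, adjusted p = 0.00338), among them the transporter SLC7A5 at 74.6 ± 6.25 and 160.0 ± 4.90 CPM. That list had an adjusted p = 0.292 with an estimated correlation.

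Of 54 interferon-stimulated genes, 32 rose and 6 fell (33 and 7 adjusted over the list alone; median 0.42, adjusted p = 4.91e-09). IFI44L rose from 7.88 ± 1.58 to 34.2 ± 2.20 CPM, the chemokine CXCL10 from 1.08 ± 0.360 to 4.27 ± 0.687 CPM and ISG15 from 38.2 ± 7.62 to 59.3 ± 5.20 CPM. IFIT1 stood at 25.1 ± 2.27 and 31.0 ± 1.61 CPM and did not pass (adjusted p = 0.0957, and 0.029 without STINGX with TGFb replicate 2, against 0.0288 to 0.25 over 13 other settings). Of 39 NF-kappaB and inflammatory genes, 10 rose and 19 fell (10 and 22 adjusted over the list alone; median -0.39, adjusted p = 1.91e-06). VCAM1, an adhesion molecule, fell from 30.4 ± 2.28 to 3.76 ± 0.429 CPM, complement C3 from 235.5 ± 10.8 to 51.5 ± 1.12 CPM, CXCL8 from 697.5 ± 17.5 to 300.7 ± 14.1 CPM and IL6 from 146.2 ± 11.9 to 86.4 ± 10.4 CPM. Of 30 cGAS-STING components, 5 rose and 6 fell (5 and 7 adjusted over the list alone; adjusted p = 0.638). STING1 rose from 63.5 ± 9.26 to 82.1 ± 4.14 CPM, CGAS from 20.4 ± 0.904 to 26.6 ± 2.01 CPM, and IFI16 fell from 190.7 ± 4.33 to 99.9 ± 2.88 CPM, while TBK1 (adjusted p = 0.532) and IRF3 (0.95) did not pass.

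Quiescent stellate cell markers fell in 11 and rose in 3 of 29 cases (13 and 4 adjusted over the list alone; median -0.50, adjusted p = 0.0041, and adjusted p = 0.143 with an estimated correlation). VIPR1 fell from 4.07 ± 0.448 to 0.398 ± 0.0628 CPM and NGFR from 5.04 ± 0.332 to 2.31 ± 0.0733 CPM. Of 13 aryl hydrocarbon receptor genes, 6 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.57, adjusted p = 0.0208, and adjusted p = 0.0749 with an estimated correlation). CYP1A1 stood at 5.64 ± 0.402 and 2.08 ± 0.451 CPM. Nuclear-encoded oxidative phosphorylation genes fell in 16 of 74 cases (15 adjusted over the list alone) and none rose (median -0.16, adjusted p = 0.00214, and adjusted p = 0.632 with an estimated correlation). With upper quartile scaling 27 fell and with library size alone 32. Glycolysis genes fell in 9 and rose in 2 of 25 cases, also adjusted over the list alone (median -0.16, adjusted p = 0.0273, and adjusted p = 0.359 with an estimated correlation), among them PKM at 1786 ± 68.2 and 1219 ± 144 CPM. The glycolysis list was at 0.0658 without control replicate 1, in a range of 0.00482 to 0.359 over its alternatives. Mitochondrially encoded messenger RNAs fell in 6 of 13 cases, also adjusted over the list alone (median -0.12, adjusted p = 0.0418, and adjusted p = 0.44 with an estimated correlation). That call was lost without control replicate 4 (0.0987), TGFb replicate 3 (0.0812), TGFb replicates 1 and 4 (0.05 each) and with a filter of 1 CPM (0.0561), in a range of 0.00233 to 0.44.

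The other lists did not pass camera. By fry, crosslinking and turnover (adjusted p = 0.00703), YAP and TEAD (3.98e-05) and NRF2 genes (0.000579) passed. So did macrophage and leukocyte (0.000237) and cholangiocyte and epithelial markers (0.000481). No other list that failed camera passed fry. Nuclear-encoded oxidative phosphorylation passed camera and did not pass fry (0.055). Matrix crosslinking and turnover had 13 members higher and 6 lower of 33 (14 and 9 adjusted over the list alone; adjusted p = 0.085), and MMP1, a collagenase, fell from 545.6 ± 33.2 to 63.1 ± 2.41 CPM. That list passed without control replicate 2 (0.0423) and without a filter on low counts (0.0442), in a range of 0.0423 to 0.418. YAP and TEAD targets had 12 higher and 8 lower of 25 (13 and 8 adjusted over the list alone; adjusted p = 0.306). CCN2 went from 79.6 ± 2.96 to 294.4 ± 3.35 CPM. NRF2 and oxidative stress genes had 8 higher and 11 lower of 27 (8 and 12 adjusted over the list alone; adjusted p = 0.0854). The unfolded protein list had 7 higher and 7 lower of 34 (8 and 7 adjusted over the list alone; adjusted p = 0.647, median 0.001, mean -0.062), and mitochondrial DNA upkeep 6 and 6 of 40 (6 and 7 adjusted over the list alone; adjusted p = 0.783, median 0.001, mean -0.13), and both tested downward. Cholesterol genes had 7 higher and 6 lower of 32 (adjusted p = 0.972, median 0.006, mean -0.045, tested upward), cell cycle genes 5 and 5 of 45 (0.848, median -0.004, mean 0.021, tested upward) and p53 targets 5 and 7 of 27 (0.647), with the same counts adjusted over the list alone. These counts depend on the scaling. With library size alone, which put the median over all genes at -0.068, YAP targets had 8 higher and 8 lower, cell cycle genes 5 and 13 and p53 targets 2 and 7. The upkeep list had 2 and 9, the unfolded protein list 4 and 10 and cholesterol genes 5 and 8, with medians of -0.062, -0.063 and -0.058, and the crosslinking median turned from 0.055 to -0.008. With upper quartile scaling YAP targets also had 8 and 8, and cell cycle genes 5 and 10.

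Markers of other cell types were tested in part. These were 4 of 18 hepatocyte and 10 of 13 endothelial markers. Of macrophage and leukocyte markers 6 of 16 were tested, and of cholangiocyte and epithelial markers 6 of 10. Hepatocyte markers were tested for 4 genes, of which SERPINA1 fell from 8.48 ± 1.33 to 5.44 ± 0.588 CPM (1 lower; 1 higher and 1 lower adjusted over the list alone; adjusted p = 0.783). Endothelial markers had 3 higher and 3 lower of 10, also adjusted over the list alone (adjusted p = 0.843, median 0.26, mean -0.047, tested upward). Macrophage and leukocyte markers had 2 higher and 3 lower of 6, also adjusted over the list alone (adjusted p = 0.289). CD14 fell from 15.7 ± 2.19 to 2.42 ± 0.483 CPM and CD68 from 59.6 ± 1.87 to 24.4 ± 2.68 CPM, and PTPRC, with 66 counts in control and 0 with TGFb, was at least 18.8-fold lower. Cholangiocyte and epithelial markers had 3 higher of 6, also adjusted over the list alone (adjusted p = 0.085, and 0.0438 without control replicate 2, in a range of 0.0438 to 0.292). Of the 25 tested panel genes, 19 passed. CCL2 (log2 change 0.16, adjusted p = 0.0469) lost its call in 10 of 13 other settings (0.0342 to 0.216) and without each of control replicates 3 and 4, TGFb replicates 1, 2 and 4, and STINGX with TGFb replicates 1, 2, 3 and 4 (0.0331 to 0.124 over all 12). With library size alone as the scaling, 2224 genes were higher and 3523 lower (38.7% higher, against 50.7%), and on log2(FPKM + 1) 1988 and 3065 (39.3%).

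**Figure D1:**
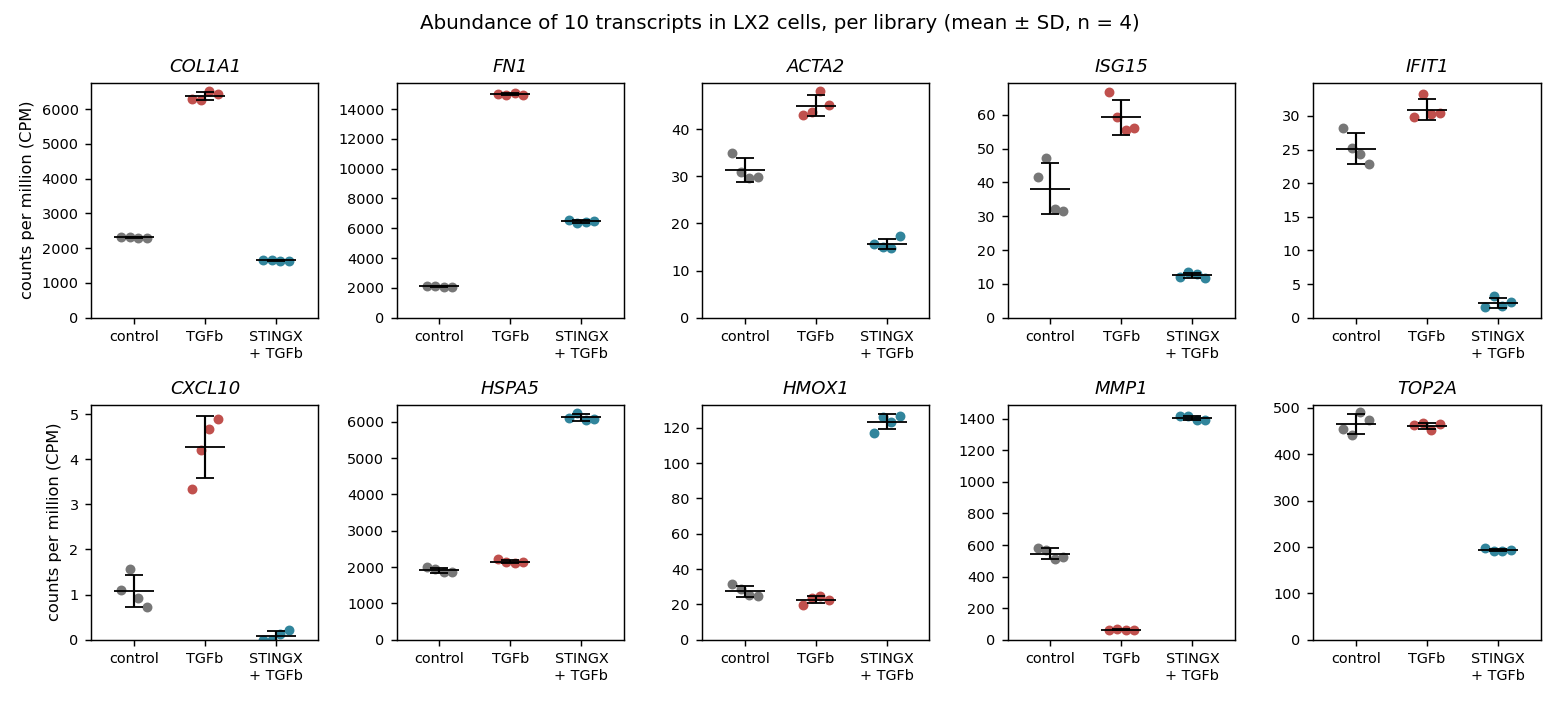
CPM of 10 genes in each library (points) of the control, TGFb and STINGX with TGFb groups, with the mean and SD of 4 libraries as bars and every axis starting at 0. FN1 stands at 2102, 15010 and 6462 CPM, ISG15 at 38.2, 59.3 and 12.6 CPM, and HSPA5 at 1916, 2152 and 6120 CPM in the 3 groups.

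The comparison of STINGX with TGFb against TGFb alone asked what the compound changed in stimulated cells. Interferon-stimulated, matrix, cell cycle and cholesterol genes were lower, and genes of the unfolded protein and oxidative stress responses were higher. COL1A1 fell from 6367 ± 121 to 1644 ± 15.2 CPM and FN1 from 15010 ± 74.3 to 6462 ± 75.7 CPM. IFIT1, which encodes an interferon-induced RNA-binding protein, fell from 31.0 ± 1.61 to 2.20 ± 0.707 CPM, and the endoplasmic reticulum chaperone gene HSPA5 rose from 2152 ± 46.0 to 6120 ± 87.4 CPM. Of 21328 genes, 5864 passed (2931 higher, 2933 lower). 589 stood at least 2-fold higher and 732 at least 2-fold lower, and groups did not overlap for 31.6% of genes.

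The largest rises were those of MMP1 (ENSG00000196611, chromosome 11, 102789919 to 102798160, log2 fold change 4.48 ± 0.05 SE, adjusted p = 3.36e-14), SERPINB2 (3.83), RPLP0P2, a ribosomal protein pseudogene by its name (3.68), MMP3 (3.63), ZNF678 (3.05) and the cytokine TSLP (2.73). The largest falls were those of FOXS1 (-6.84 ± 0.28, adjusted p = 3.19e-12), CXCL11 (-5.58), PRAL (-5.11), ISLR2 (-4.98), OASL (-4.91) and IFIT1 (-3.81). MMP1 overlaps WTAPP1, PRAL overlaps XAF1 and IFIT1 overlaps LIPA on the opposite strand, and RPLP0P2 could share reads with its parent gene. ZNF678 and TSLP, on the opposite strand, and CXCL11, on both strands, overlap only genes that were not tested. The fall of PRAL (adjusted p = 0.0134) did not pass with limma-voom (adjusted p = 0.193), in a range of 6.35e-05 to 0.193 over 13 settings. Its log2 change became -4.19 without TGFb replicate 4 and -6.37 without STINGX with TGFb replicate 1, so its place among the falls depends on single libraries. That of CXCL11 became -7.46 without STINGX with TGFb replicate 3 and that of ZNF678 3.92 without TGFb replicate 3.

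Of 54 interferon-stimulated genes, 48 fell and none rose (50 and 0 adjusted over the list alone; median -1.42, adjusted p = 3.92e-55). CXCL10 fell from 4.27 ± 0.687 to 0.0872 ± 0.107 CPM, OASL from 30.7 ± 1.16 to 1.03 ± 0.291 CPM and ISG15 from 59.3 ± 5.20 to 12.6 ± 0.746 CPM. CXCL10 had 0, 0, 8 and 15 counts in the STINGX with TGFb libraries. Its log2 change was -5.64, and -6.72 without STINGX with TGFb replicate 4. RSAD2, with 208 counts under TGFb and 0 with STINGX, was at least 86.2-fold lower, and the list median with that bound was -1.42. NF-kappaB and inflammatory genes fell in 21 and rose in 7 of 39 cases (22 and 8 adjusted over the list alone; median -0.46, adjusted p = 0.000197). The chemokines CCL5, from 177.1 ± 9.78 to 12.7 ± 2.76 CPM, and CCL2, from 227.6 ± 10.3 to 35.3 ± 1.66 CPM, fell, while CXCL8 rose from 300.7 ± 14.1 to 739.5 ± 7.59 CPM and IL33 from 0.253 ± 0.0434 to 1.37 ± 0.552 CPM. Of 30 cGAS-STING components, 4 rose and 6 fell (4 and 7 adjusted over the list alone; adjusted p = 0.397), and the median of -0.016 became 0.125 with library size alone (7 higher, 4 lower). STING1 fell from 82.1 ± 4.14 to 48.4 ± 0.678 CPM and IRF7 from 23.0 ± 1.81 to 11.9 ± 0.798 CPM, while CGAS (adjusted p = 0.74), TBK1 (0.508) and IRF3 (0.924) did not pass. TBK1 passed in 4 of 13 other settings (0.0137 to 0.601 over all 13), with a log2 change of 0.193 under library size alone in place of 0.053. CGAS (log2 change 0.037) passed on log2(FPKM + 1) with 0.148 and on log2(FPKM + 0.1) with 0.173 (adjusted p from 0.046 to 0.814 over 13).

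Of 30 fibrillar collagens and matrix glycoproteins, 23 fell and none rose (24 and 0 adjusted over the list alone; median -1.21, adjusted p = 1.03e-35). COL4A1, a basement membrane collagen, fell from 1210 ± 24.2 to 228.1 ± 19.8 CPM and THBS1 from 915.9 ± 9.63 to 260.1 ± 6.62 CPM. Matrix crosslinking and turnover genes fell in 22 and rose in 4 of 33 cases (25 and 4 adjusted over the list alone; median -0.59, adjusted p = 9.94e-12). LOXL4 fell from 10.8 ± 0.871 to 3.16 ± 0.674 CPM, whereas the metalloproteinases MMP1, from 63.1 ± 2.41 to 1407 ± 14.2 CPM, and MMP3, from 0.356 ± 0.214 to 4.48 ± 1.07 CPM, rose. Of 39 SMAD targets, 29 fell and 2 rose (30 and 3 adjusted over the list alone; median -0.67, adjusted p = 2.06e-24). PDGFB went from 98.1 ± 5.20 to 13.4 ± 0.819 CPM. Contractile genes fell in 13 of 27 cases and none rose, also adjusted over the list alone (median -0.24, adjusted p = 8.22e-09). ACTA2 went from 45.0 ± 2.27 to 15.7 ± 1.07 CPM. YAP and TEAD targets fell in 13 and rose in 6 of 25 cases (15 and 7 adjusted over the list alone; median -0.23, adjusted p = 0.00478). CCN2 went from 294.4 ± 3.35 to 124.4 ± 2.61 CPM. Integrin and focal adhesion genes fell in 13 and rose in 3 of 23 cases (14 and 3 adjusted over the list alone; median -0.36, adjusted p = 3.74e-06). ITGA11 went from 59.9 ± 3.37 to 9.04 ± 0.862 CPM.

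Of 34 unfolded protein and integrated stress response genes, 28 rose and 1 fell (30 and 1 adjusted over the list alone; median 0.57, adjusted p = 7.43e-23). With an estimated correlation the camera adjusted p was 0.00442. TRIB3 rose from 41.5 ± 2.35 to 151.1 ± 4.37 CPM, DDIT3, which encodes the transcription factor CHOP, from 29.5 ± 10.6 to 85.2 ± 24.2 CPM, and PPP1R15A from 235.1 ± 4.04 to 621.6 ± 11.6 CPM. NRF2 and oxidative stress genes rose in 17 and fell in 1 of 27 cases (21 and 3 adjusted over the list alone; median 0.60, adjusted p = 8.59e-12). HMOX1, heme oxygenase, rose from 22.7 ± 2.14 to 123.3 ± 4.28 CPM, NQO1 from 23.7 ± 4.11 to 71.6 ± 0.475 CPM and the cystine transporter SLC7A11 from 25.8 ± 1.59 to 84.0 ± 2.34 CPM. Aryl hydrocarbon receptor genes rose in 6 and fell in 1 of 13 cases, also adjusted over the list alone (median 0.55, adjusted p = 0.00249). CYP1A1 went from 2.08 ± 0.451 to 6.39 ± 0.597 CPM.

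Cell cycle genes fell in 33 and rose in 1 of 45 cases (36 and 2 adjusted over the list alone; median -0.60, adjusted p = 5.01e-24). TOP2A, a topoisomerase, fell from 461.6 ± 6.50 to 193.0 ± 2.81 CPM and KIF20A from 134.0 ± 4.20 to 44.3 ± 1.65 CPM. Cholesterol genes fell in 23 and rose in 1 of 32 cases (26 and 1 adjusted over the list alone; median -0.79, adjusted p = 1.47e-23). SCD, a fatty acid desaturase gene on that list, went from 1196 ± 30.4 to 433.9 ± 4.99 CPM. Glycolysis genes fell in 14 and rose in 1 of 25 cases (16 and 1 adjusted over the list alone; median -0.51, adjusted p = 9.95e-10). LDHA went from 807.0 ± 84.3 to 424.8 ± 12.4 CPM. Mitochondrially encoded messenger RNAs fell in 11 of 13 cases and none rose, also adjusted over the list alone (median -0.36, adjusted p = 7.17e-08). With an estimated correlation the camera adjusted p was 0.0346. MT-CO2 went from 8061 ± 267 to 5234 ± 138 CPM. Nuclear-encoded oxidative phosphorylation genes fell in 28 of 74 cases and none rose (30 and 0 adjusted over the list alone; median -0.19, adjusted p = 2.69e-06). COX8A went from 136.8 ± 5.24 to 78.5 ± 2.87 CPM. That list had an adjusted p = 0.377 with an estimated correlation, and with library size alone 5 of its members were higher and 14 lower, with a median of -0.047.

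Lists that did not pass were mitochondrial DNA upkeep (2 higher and 7 lower of 40, also adjusted over the list alone; adjusted p = 0.161), serine, proline and glutamine metabolism (8 and 7 of 25; 8 and 8 adjusted over the list alone; adjusted p = 0.44), p53 targets (4 and 9 of 27, also adjusted over the list alone; 0.324) and quiescent stellate cell markers (9 and 7 of 29; 9 and 8 adjusted over the list alone; 0.635). The upkeep list had a median of -0.10, a mean of 0.021 and a downward test, the serine list -0.019, 0.096 and an upward test, and the quiescent list -0.043, 0.12 and an upward test. With library size alone the medians of the upkeep, serine, p53 and quiescent lists turned to 0.039, 0.122, 0.069 and 0.098. Members higher and lower were then 5 and 3, 10 and 4, 5 and 4, and 9 and 5, and each median stayed below that of all genes. SLC3A2, an amino acid transporter subunit, rose from 212.3 ± 20.5 to 1294 ± 114 CPM, and PDGFRB fell from 169.2 ± 5.44 to 52.7 ± 2.34 CPM. Among markers of other cell types, cholangiocyte and epithelial genes fell in 5 and rose in 1 of 6 cases, also adjusted over the list alone (median -0.86, adjusted p = 0.000986). KRT8 went from 166.8 ± 4.03 to 86.8 ± 4.20 CPM and SPP1 from 1.87 ± 0.261 to 7.72 ± 0.724 CPM. Hepatocyte (0 and 1 of 4, also adjusted over the list alone; adjusted p = 0.346), endothelial (3 and 3 of 10; 3 and 4 adjusted over the list alone; 0.221) and macrophage markers (1 and 1 of 6, also adjusted over the list alone; 0.324) did not pass, though CD68 rose from 24.4 ± 2.68 to 75.9 ± 7.99 CPM and FLT1 fell from 84.3 ± 2.05 to 39.1 ± 1.59 CPM. By fry, every list that did not pass camera in this comparison passed, except the quiescent list (adjusted p = 0.65). For the others the adjusted p ran from 4.45e-07 for endothelial markers to 0.0466 for cGAS-STING components. Of 25 tested panel genes, 19 passed. With library size alone, 4997 genes were higher and 1890 lower (72.6% higher, against 50%), and on log2(FPKM + 1) 4408 and 1652 (72.7%). Library size alone put the median over all genes at 0.147. No list that passed camera had a median of the other sign under any of the 4 scalings, nor relative to that shift.

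**Figure D2:**
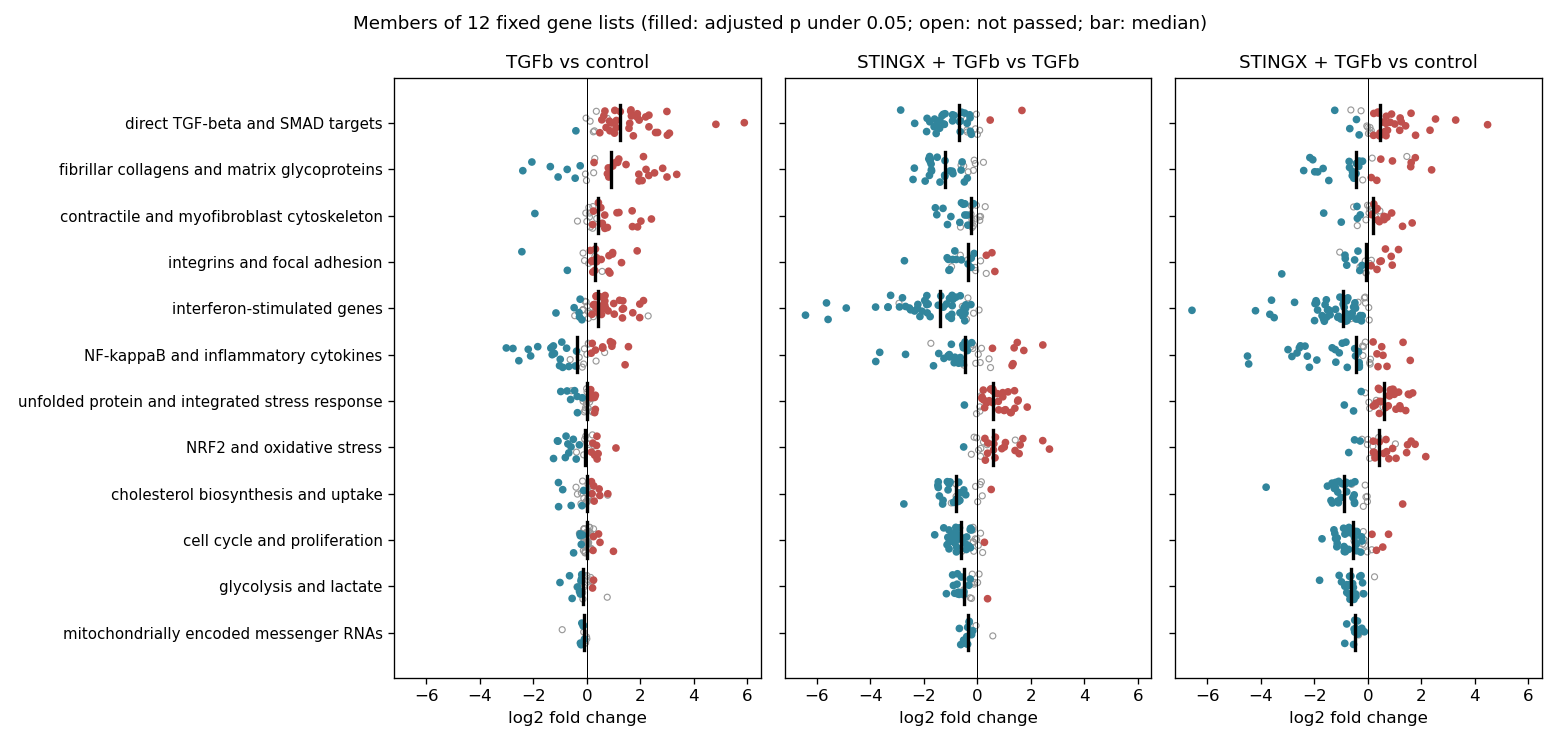
Log2 fold changes of the members of 12 gene lists in the 3 comparisons, each point 1 gene (filled red, passed and higher; filled blue, passed and lower; open, not passed), with a bar at the list median. Interferon-stimulated genes lie around a median of 0.42 for TGFb against control, -1.42 for STINGX with TGFb against TGFb and -0.92 for STINGX with TGFb against control.

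The comparison of STINGX with TGFb against control asked where the pretreated cells stood relative to untreated ones. SMAD targets stayed higher than in control, while interferon-stimulated genes, glycolysis, cholesterol and cell cycle genes were lower than in control. FN1, of the matrix glycoprotein list, was also higher (6462 ± 75.7 against 2102 ± 36.4 CPM). Of the 30 tested genes of that list, 19 were lower and 8 higher. COL1A1 was lower (1644 ± 15.2 against 2307 ± 16.4 CPM), as was IFIT1 (2.20 ± 0.707 against 25.1 ± 2.27 CPM). HSPA5 was higher (6120 ± 87.4 against 1916 ± 68.1 CPM). Of 21328 genes, 7296 passed (3670 higher, 3626 lower). 681 stood at least 2-fold higher and 936 at least 2-fold lower, and groups did not overlap for 34.5% of genes.

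The largest rises were those of ZNF778 (ENSG00000170100, chromosome 16, 89217703 to 89237071, log2 fold change 4.15 ± 0.60 SE, adjusted p = 0.000311), EPHB1 (3.54), CALB2 (3.47), SH2D2A (3.33), PMEPA1 (3.28) and ZBTB37 (3.20). Among the largest falls were those of MIR155HG (-6.18), VCAM1 (ENSG00000162692, chromosome 1, 100719742 to 100739045, -4.46 ± 0.14, adjusted p = 3.31e-10), OASL (-4.20), CXCL11 (-3.60) and IFIT1 (-3.51). EPHB1 overlaps KY and ZBTB37 overlaps GAS5 on the opposite strand. ZNF778 and CALB2, on the opposite strand, and MIR155HG, on its own, overlap only genes that were not tested. The fall of MIR155HG (adjusted p = 0.000726) did not pass with limma-voom (adjusted p = 0.246), in a range of 1.11e-06 to 0.246 over 13 settings, and its log2 change became -7.04 without STINGX with TGFb replicate 4. That of CXCL11 became -5.48 without STINGX with TGFb replicate 3.

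Of 39 SMAD targets, 26 rose and 4 fell, also adjusted over the list alone (median 0.45, adjusted p = 6.6e-14). NOX4 stood at 1.06 ± 0.215 against 0.0475 ± 0.0611 CPM, INHBA at 133.1 ± 15.9 against 26.6 ± 2.21 CPM and SMAD7 at 59.3 ± 3.72 against 17.3 ± 3.00 CPM. The log2 change of NOX4 was 4.48, and 5.59 without control replicate 1. Contractile genes rose in 12 and fell in 5 of 27 cases (13 and 5 adjusted over the list alone; median 0.17, adjusted p = 0.0175, and adjusted p = 0.0625 with an estimated correlation). TAGLN was higher (241.4 ± 23.4 against 98.3 ± 9.71 CPM) and ACTA2 lower (15.7 ± 1.07 against 31.3 ± 2.5 CPM). Collagens and matrix glycoproteins fell in 19 and rose in 8 of 30 cases (20 and 10 adjusted over the list alone; median -0.44, adjusted p = 0.000303). COL3A1 stood at 183.1 ± 5.39 against 584.4 ± 15.2 CPM and LUM at 2.14 ± 0.378 against 11.3 ± 1.17 CPM. Crosslinking and turnover genes fell in 17 and rose in 7 of 33 cases (17 and 10 adjusted over the list alone; median -0.33, adjusted p = 0.00166, and adjusted p = 0.146 with an estimated correlation). TGM2 stood at 28.98 ± 1.09 against 100.6 ± 5.51 CPM and MMP1 at 1407 ± 14.2 against 545.6 ± 33.2 CPM. Quiescent markers fell in 11 and rose in 3 of 29 cases, also adjusted over the list alone (median -0.14, adjusted p = 0.0188, and adjusted p = 0.162 with an estimated correlation). A filter of 1 CPM gave 0.0506 for that list, in a range of 0.00449 to 0.162.

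Of 54 interferon-stimulated genes, 47 were lower than in control and none higher, also adjusted over the list alone (median -0.92, adjusted p = 2.64e-34). OASL stood at 1.03 ± 0.291 against 18.9 ± 3.25 CPM and ISG15 at 12.6 ± 0.746 against 38.2 ± 7.62 CPM, and RSAD2 was at least 95.6-fold lower (0 against 270 counts). NF-kappaB and inflammatory genes fell in 24 and rose in 8 of 39 cases (24 and 9 adjusted over the list alone; median -0.46, adjusted p = 7.54e-11). CCL2 stood at 35.3 ± 1.66 against 203.2 ± 14.2 CPM, IL6 at 62.7 ± 2.49 against 146.2 ± 11.9 CPM and CCL5 at 12.7 ± 2.76 against 91.1 ± 24.8 CPM. CXCL8 stood at 739.5 ± 7.59 against 697.5 ± 17.5 CPM and did not pass (log2 change 0.084, adjusted p = 0.0928). It passed in 4 of 13 other settings (0.00106 to 0.48 over all 13), among them library size alone (log2 change 0.162). STING1 was lower (48.4 ± 0.678 against 63.5 ± 9.26 CPM) and CGAS higher (27.2 ± 1.28 against 20.4 ± 0.904 CPM), while the cGAS-STING list had 4 higher and 8 lower of 30, also adjusted over the list alone (adjusted p = 0.109, and 0.0413 without a filter on low counts, in a range of 0.0413 to 0.296).

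Unfolded protein genes rose in 25 and fell in 3 of 34 cases (27 and 3 adjusted over the list alone; median 0.62, adjusted p = 2.39e-16). The chaperone HYOU1 stood at 1357 ± 133 against 462.8 ± 70.1 CPM and DNAJB9 at 91.4 ± 1.30 against 34.3 ± 2.07 CPM. NRF2 genes rose in 17 and fell in 3 of 27 cases (17 and 4 adjusted over the list alone; median 0.41, adjusted p = 1.26e-06). HMOX1 stood at 123.3 ± 4.28 against 27.5 ± 3.08 CPM and GCLM at 78.0 ± 2.28 against 27.9 ± 2.10 CPM. Serine, proline and glutamine genes rose in 13 and fell in 7 of 25 cases, also adjusted over the list alone (median 0.22, adjusted p = 0.00166, and adjusted p = 0.171 with an estimated correlation). SLC3A2 stood at 1294 ± 114 against 164.0 ± 11.6 CPM. Cholesterol genes fell in 25 and rose in 1 of 32 cases, also adjusted over the list alone (median -0.89, adjusted p = 6.75e-21). IDI1 stood at 38.1 ± 15.5 against 109.2 ± 2.5 CPM. Cell cycle genes fell in 33 and rose in 4 of 45 cases (35 and 4 adjusted over the list alone; median -0.56, adjusted p = 8.37e-19). TOP2A stood at 193.0 ± 2.81 against 465.7 ± 21.7 CPM. Glycolysis genes fell in 22 of 25 cases and none rose, also adjusted over the list alone (median -0.62, adjusted p = 1.91e-14). PGK1 stood at 465.2 ± 20.8 against 922.7 ± 57.8 CPM. Mitochondrially encoded messenger RNAs fell in 12 of 13 cases, also adjusted over the list alone (median -0.47, adjusted p = 2.33e-10). MT-CO2 stood at 5234 ± 138 against 9535 ± 529 CPM. Nuclear-encoded oxidative phosphorylation genes fell in 52 and rose in 1 of 74 cases (55 and 1 adjusted over the list alone; median -0.34, adjusted p = 2.08e-12, and adjusted p = 0.174 with an estimated correlation). SDHA stood at 241.3 ± 10.4 against 405.0 ± 19.5 CPM.

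Lists that did not pass were YAP and TEAD targets (6 higher and 12 lower of 25; adjusted p = 0.105, and 0.0413 without a filter on low counts, in a range of 0.0413 to 0.207), mitochondrial DNA upkeep (5 and 9 of 40; 0.124) and p53 targets (2 and 9 of 27; 0.109), with the same counts adjusted over the list alone. The p53 list passed without control replicate 3 (0.0474) and without a filter (0.0377), in a range of 0.0377 to 0.296. Integrins had 8 higher and 8 lower of 23 (9 and 8 adjusted over the list alone; adjusted p = 0.53), and aryl hydrocarbon receptor genes 5 and 2 of 13 (5 and 3 adjusted over the list alone; 0.214, median -0.098, mean -0.15, tested upward). With library size alone the medians of the YAP and integrin lists turned from -0.065 and -0.075 to 0.007 and 0.003, and 12 crosslinking genes rose in place of 7. Upper quartile scaling gave 4 higher and 15 lower upkeep genes. Cholangiocyte and epithelial markers fell in 4 and rose in 1 of 6 cases, also adjusted over the list alone (median -0.61, adjusted p = 0.0483, and adjusted p = 0.151 with an estimated correlation). That call was lost without control replicate 2 (0.0736), TGFb replicate 4 (0.0534), STINGX with TGFb replicates 1 (0.069) and 3 (0.0577) and with a filter of 1 CPM (0.0814), in a range of 0.0271 to 0.151. Hepatocyte (0 and 1 of 4; adjusted p = 0.297), endothelial (2 and 3 of 10; 0.26) and macrophage markers (3 and 2 of 6; 0.727, median 0.18, mean -0.33, tested upward) did not pass, with the same counts adjusted over the list alone, and CD14 was lower (2.30 ± 0.445 against 15.7 ± 2.19 CPM). Of 25 tested panel genes, 19 passed. TIMP1 (log2 change 0.23, adjusted p = 0.0466) lost its call in 6 of 13 other settings (0.0054 to 0.105) and without each of control replicates 3 and 4, TGFb replicates 1, 2, 3 and 4, and STINGX with TGFb replicates 2 and 3 (0.0159 to 0.139 over all 12). By fry, every list that did not pass camera in this comparison passed, except macrophage and leukocyte markers (adjusted p = 0.96). For the others the adjusted p ran from 3.22e-06 for YAP and TEAD targets to 0.0125 for integrins. With library size alone, 4683 genes were higher and 2876 lower (62.0% higher, against 50.3%), and on log2(FPKM + 1) 4286 and 2484 (63.3%).

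Genes that TGFb changed were followed into the STINGX group with 2 of the TGFb libraries used for choosing them and the other 2 for measuring. Of genes raised by TGFb, 71% (69.4 to 71.7% over 6 halvings) moved toward the control level, with a median shift of -0.201 on the log2 scale, and of genes lowered 66.9% (64.5 to 68.0%) did so, with a median shift of 0.197. Simulated counts without a STINGX effect gave 48.5% and 50.5%. The median shift toward control, as a share of the TGFb change, was 33.2% for raised and 27.2% for lowered genes. With library size alone the shares were 19.2% and 44.7%, so their order depends on the scaling. The TGFb change was measured in the libraries that chose the genes, which can enlarge it and make these shares too low. Without a group given STINGX alone, a reversal of the TGFb effect cannot be told from a separate effect in the opposite direction. FN1 and SMAD7 lay between control and TGFb, and COL1A1, ACTA2 and ISG15 lay below control. With the same 4 TGFb libraries in both comparisons, 1180 genes rose with TGFb and fell with STINGX (41.9% of those raised) and 1010 fell and then rose (37.0% of those lowered), where independent lists give 386.8 and 375.2. With the TGFb libraries halved the counts were 829 and 623 on average, where independent lists give 227 and 189. The covariance of the fold changes over 13646 genes was -0.124 (r = -0.428), and in simulated groups -0.036 (r = -0.477). Against the shared control, 1609 genes were higher in both comparisons (57.2% of those raised by TGFb) and 1558 lower in both (57.1%), where independent lists give 484 and 464.1. With the control libraries split the counts were 1109.5 and 1066.7, where independent lists give 316.9 and 296.4. Simulated groups without effects had 0 to 0.2 calls in each direction, so their overlaps of 0 to 0.1 genes give no chance level for these counts. The covariance was 0.187 (r = 0.582) with the shared control, 0.156 (r = 0.414) with it split, and 0.038 (r = 0.492) in simulated groups. These correlations are across genes, which are not independent replicates.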

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

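The tests of scaling and of a return to the untreated level were chosen after their results were seen, as was the second way of counting XBP1 transcripts. The splits of the libraries, the test of abundant genes, the first XBP1 test and the tests of same-strand overlaps were set beforehand. The shares for opposite-strand overlaps and pseudogenes, and the reference of genes without overlaps, were added after the other results were seen.

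In 11 of 174 checks of 4 libraries (6.3%) 1 library lay far from the other 3 of its group, by Dixon's criterion, and chance marks about 1 in 20 groups. EGR2 stood at 43.42 CPM in TGFb replicate 1 and at 37.67 to 38.42 CPM in the others. TBK1 stood at 40.9 CPM in the same library and at 43.64 to 43.94 CPM in the others. IFIT1 stood at 33.33 CPM in TGFb replicate 2 (others 29.83 to 30.41 CPM), and PCDHGA8 at 1.144 CPM there (others 0.1 to 0.173 CPM). ZNF678 stood at 2.066 CPM in TGFb replicate 3 (others 0.29 to 0.577 CPM), and the 10 most abundant genes took 10.11% of its counts (others 10.22 to 10.24%). In TGFb replicate 4, UNC5B stood at 23.37 CPM (others 24.96 to 25.27 CPM), EVI2B at 1.673 CPM (others 1.0 to 1.11 CPM) and PRAL at 24.39 CPM (others 4.135 to 5.874 CPM). SERPINB2 stood at 392.5 CPM in STINGX with TGFb replicate 1 (others 540.5 to 545.8 CPM). The mitochondrial share of STINGX with TGFb replicate 4 was 8.46% (others 8.16 to 8.21%).

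Counts of single transcripts, which the comparisons of genes did not use, were examined for XBP1 only. The spliced form of XBP1, made by the endoplasmic reticulum sensor IRE1, took 38.92 ± 11.03% of its transcripts in control, 49.85 ± 6.66% with TGFb and 67.21 ± 2.58% with STINGX and TGFb (SD, n = 4). Without the transcript that retains an intron the shares were 61.92 ± 26.31%, 80.05 ± 14.88% and 76.07 ± 14.42%. STINGX with TGFb stood 28.29 points above control in the first counting (exact permutation test, p = 0.0286, 0.0429 adjusted) and 14.14 points in the second (exact p = 0.371), so a level above untreated cells depends on that transcript.

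The first pattern weighed was the rise of the unfolded protein and NRF2 lists with STINGX. The largest shift of the median of all genes between scalings was 0.151, against list medians of 0.57 and 0.60, which argues against scaling as the whole cause. The median of the unfolded protein list against untreated cells was 0.616, which argues against a mere return of a TGFb effect for that list. TGFb had left that list near control (median 0.001), so this value adds little to the rise over TGFb. The NRF2 list was not put to this test. Its median was 0.405 against untreated cells and 0.602 against TGFb, and TGFb lowered 11 and raised 8 of its 27 members. A partial return is not excluded for the NRF2 list. An active IRE1 branch may contribute, since the spliced XBP1 share rose by 17.36 percentage points over TGFb (exact permutation test, two-sided, n = 4 per group, p = 0.0286, the smallest the design can give, and 0.0429 adjusted over 3 comparisons). Without the transcript that retains an intron the difference was -3.98 points (exact p = 0.657), so whether the branch was active cannot be told apart from a shift in that transcript.

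The second pattern was that interferon-stimulated genes lay below untreated cells after STINGX with TGFb. Of the 54 tested members, 46 had at least 10 CPM in untreated cells. Their median was -0.916, as was that of the whole list, and 41 of them were lower. The falls thus lay mostly in genes well above the floor, which argues against low counts. These 46 genes are most of the list, so their median is not a separate test. The largest shift of the median of all genes between scalings was 0.128, far less than the list median. A direct effect of the compound on baseline interferon signalling may be a candidate explanation, and without a group given STINGX alone it stays untested.

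The third pattern was that pseudogenes and overlapping genes stood among the largest changes. Fold changes of 2681 pairs that overlap on the same strand had a Spearman rho of 0.17 (0.135 to 0.208) across genes. That is not the negative rho set beforehand as the mark of counts moved from 1 gene to the other. Reads credited to a neighbour can also give both genes the same change, and so a positive rho. The test therefore cannot exclude uncertain assignment. The interval treats pairs as independent, though some genes recur in several. At 2 CPM or more, 3.99% of 4712 genes that overlap on the same strand and 4.84% of 8934 others changed at least 2-fold, a ratio of 0.825 (0.698 to 0.976). Of 4014 genes that overlap none and are no pseudogenes by biotype, 5.41% did so. Against these the ratio was 0.74 (0.61 to 0.893) for same-strand overlaps, 0.83 (0.69 to 0.997) for overlaps on the opposite strand only and 0.42 (0.219 to 0.816) for 394 pseudogenes. No class had a larger share of large changes than its reference. The classes were not matched for abundance or spread beyond the minimum of 2 CPM. The ratios therefore cannot exclude that uncertain assignment raised the number of large changes within a class. Single genes such as PCDHGA8 and RPLP0P2, which the file does not class as a pseudogene, stay open.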

How the results depend on the processing

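Of the 35 ways to split 8 libraries into 4 and 4, 1 gave as many genes as the real split in each comparison, the real one itself. That share, 1 of 35, is the smallest they can give and lies under 5%, so chance can be excluded at that level only. Other splits mix groups that differ, which adds to their spread, so their low counts do not measure chance calls. The real counts were 5543, 5864 and 7296, and the highest of the other splits 7, 3 and 3. Over 13 other settings the counts ran from 4815 to 6044 for TGFb against control, from 5252 to 6887 for STINGX with TGFb against TGFb and from 6526 to 7559 for STINGX with TGFb against control. With 1 library left out they ran from 4850 to 5342, 5056 to 5913 and 6418 to 7236, and at least 83.5%, 82.8% and 84.6% of the genes were shared with the same direction, against at least 75.1%, 69.2% and 76.9% over the other settings. With an estimated correlation 6 and 10 lists passed against control in place of 12 and 16, and 16 in place of 17 for STINGX with TGFb against TGFb. Lists that kept their call had far larger camera adjusted p than at the preset correlation. For STINGX with TGFb against TGFb it was 4.48e-06 for interferon-stimulated, 0.000737 for cell cycle and 0.0192 for NF-kappaB and inflammatory genes.

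The median shift of genes raised by TGFb (-0.201) became -0.175 with a filter of 1 CPM and -0.131 with library size alone, and -0.22 to -0.213 without 1 STINGX with TGFb library. The shift of lowered genes (0.197) became 0.175 with a filter of 1 CPM, 0.288 with library size alone and 0.22 with the same 4 TGFb libraries in both comparisons. Less the median of all genes, library size alone gave -0.278 and 0.141. The cause of the other differences was not tested. Of 127, 119 and 125 named genes, 116, 113 and 116 kept their side of the threshold under every setting and left-out library run that could test them, and none reversed. Some settings could not test every named gene. Genes under about 2-fold were recovered least often in simulated counts, which limits calls of small changes.

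With the replicate number as a block, 5316, 5647 and 7116 genes passed, and the shift of raised genes was -0.23. Deviations of libraries with the same number had r from -0.031 to 0.074 across genes (12 pairs, mean 0.028), and of other pairs -0.111 to 0.114 (mean -0.01). No pair with the same number exceeded 0.1, so the numbers were not taken to pair the samples. Of 24 best matches 11 had their own number, where chance gives 6, so a weak pairing is not excluded.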

Other observations

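The Gene Ontology terms were all tested after the main results were seen, and the terms named were chosen by their values. Of 2462 terms, 53 passed for TGFb against control, 219 for STINGX with TGFb against TGFb and 178 for STINGX with TGFb against control, and 0, 28 and 0 passed with an estimated correlation. With TGFb, complement activation genes fell in 10 of 16 cases and none rose (median -1.04, camera adjusted p = 1.95e-08, and adjusted p = 0.13 with an estimated correlation). Ribosome biogenesis genes rose in 47 and fell in 5 of 103 cases (median 0.19, adjusted p = 0.000701, and adjusted p = 0.447 with an estimated correlation).

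With STINGX, laminin binding genes fell in 16 and rose in 1 of 24 cases (median -0.60, adjusted p = 1.6e-10, and adjusted p = 0.016 with an estimated correlation). Chromosome condensation genes fell in 12 of 21 cases (median -0.47, adjusted p = 1.78e-07, and adjusted p = 0.0203 with an estimated correlation), and mitotic spindle assembly checkpoint genes in 13 of 22 (median -0.26, adjusted p = 1.91e-06, and adjusted p = 0.0256 with an estimated correlation). No gene of the last 2 terms passed upward. Against control, nucleosome genes fell in 40 and rose in 6 of 76 cases (median -0.79, adjusted p = 1.08e-08, and adjusted p = 0.0951 with an estimated correlation).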
